A study of Mus musculus with 12 samples.

How the data were processed

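The values were the deposited table of 41345 probe sets on 12 arrays. The series record gave the design as 3 mice per group, and the sample labels gave the group names, dorsal skin of Mus musculus, total RNA, biotin label, the extraction kit with a DNase step and the labelling kit for whole transcripts. The scale was read as log2 from the range of the deposited values; how the authors summarized and normalized the arrays was not given in the sources used here. Array medians lay between 5.35 and 5.43, and no further normalization was applied. The UV dose, the time from exposure to sampling, sex, age and strain were not given in the sources used here. Per the labels UVB exposure took place in a sterile environment.

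Probe sets were named by a supplied annotation table. It listed 25335 probe sets, 23521 of them with 1 gene symbol, which were used, and 1814 with several, which were not; 16010 were not listed and were not used for genes. Of the 23521, 23328 matched the reference gene table by gene identifier, and all 23328 had the same symbol there. For the 1082 genes with more than 1 probe set the probe set with the highest mean over all 12 arrays was taken, which left 22180 genes.

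Groups were compared in limma 3.58.1 under R 4.3.3 with 1 mean per group, equal weights and empirical Bayes variances (8 residual degrees of freedom). The comparisons were UV in SPF skin, UV in GF skin, the difference of these 2 effects, GF against SPF skin without UV and after UV, and the mean UV effect. Tests were two-sided, p values were adjusted by the method of Benjamini and Hochberg over all genes, and a gene was called at adjusted p below 0.05. A gene called in a list was tested over all genes, and a second count adjusted p over the members of that list alone.

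Gene lists were tested with camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the residuals, and with fry, a rotation test, for direction and for mixed changes; p was adjusted over the lists of each comparison. The 33 lists held 808 genes, of which 720 were measured, 5 to 35 per list. The lists, the comparisons, the thresholds, the fixed genes of interest, the rule for naming genes and the alternatives, except that without the GF UV- group, were chosen before the data were examined. By that rule the named genes were the 10 largest rises and 10 largest falls among called genes of a comparison, at most 4 members of each list with the smallest p, and the fixed genes. Gene functions are general knowledge.

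The UV effects of the 2 housings were compared by correlation and covariance over all genes, and by the median difference of effect size over the genes called for the mean UV effect, with an exact test over all 400 assignments of housing labels within the UV states. Independent overlap was the product of the 2 list sizes over 22180. Chance splits reassigned mice between the groups compared, 10 splits for 3 against 3 and 100 drawn for the comparison of UV effects. Likeness between comparisons that share mice was set against 20 simulations of unchanged groups with the variance of each gene.

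The procedure was tested on simulated data with 200 changed genes of 22180 and the sample numbers of this series. It recovered 95.0%, 91.0%, 72.0%, 84.0% and 87.0% of 1 log2 changes for UV in SPF skin, UV in GF skin, the difference of effects, GF against SPF without UV and after UV, and 96.0% to 100% of 2 log2 changes, with 4.00% to 7.07% false calls. The size comparison recovered a median of -0.51 log2 for a GF effect simulated at 0.6 of the SPF effect (1642 genes, exact permutation p = 0.0850) and 0.01 log2 for equal effects (1806 genes, exact permutation p = 0.0700), so the requirement on its p was dropped and only the median was kept as a measure. The filter on gene names without a function was first wider than the rule and was trimmed to it, after which everything was run again. Figures were drawn with matplotlib 3.10.9, and array weights used statmod 1.5.0.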

Results

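Dorsal skin of specific-pathogen-free (SPF) and germ-free (GF) mice was compared with and without ultraviolet B exposure (UV), with 3 mice and 3 arrays in each of 4 groups. The series asked how the skin microbiome modulates the response to UV. In SPF skin UV changed 5230 of 22180 genes, and in GF skin it changed 6155. Of these 6155 genes, 4201 also differed between unexposed GF and SPF skin with the opposite sign. Both comparisons use the unexposed GF mice, so the GF count depends on the level of those skins. Without UV, 8441 genes differed between GF and SPF skin, and after UV 26 did. The count after UV depended on the setting. It was 1444 without GF UV+ replicate 2, 602 with array weights and 1 with only the 2 groups compared. The unexposed GF skins carried most of the variation: the 1st principal component held 58.9% of the variance and placed these 3 arrays at 65.5 to 78.3, with all 9 others below zero. Changes are log2 differences of group means with their standard error (SE) from limma, all p values are two-sided, and adjusted p is over all genes unless a list is named.

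In SPF skin UV raised the wound keratins Krt6b by 6.07 log2 (SE 0.24, 67.2-fold), Krt16 by 4.87 log2 (SE 0.12, 29.3-fold) and Krt6a by 2.65 log2 (SE 0.18, 6.29-fold), filaments that keratinocytes make in injured epidermis (n = 3 mice per group). The acute phase gene Saa3 had the largest rise, 6.23 log2 (SE 0.74, 75.3-fold, adjusted p = 0.000111). Il1b, which encodes a cytokine that starts skin inflammation, rose by 5.39 log2 (SE 0.39, 42.0-fold, adjusted p = 4.24e-06). The cornified envelope gene Sprr1b rose by 5.38 log2 (SE 0.36), and the growth factor genes Epgn and Hbegf, whose products bind the epidermal growth factor receptor, rose by 4.26 log2 (SE 0.22) and 2.67 log2 (SE 0.15). Of 28 measured genes of the stress keratin and wound list 24 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. Its mean change was 1.99 log2 (camera adjusted p = 9.19e-18), and adjusted p = 0.0444 with an estimated correlation.

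Transcripts of the DNA damage response rose in SPF skin. The p53 targets Pmaip1 and Tnfrsf10b, which promote apoptosis, rose by 2.17 log2 (SE 0.16) and 2.07 log2 (SE 0.11), and Cdkn1a, which arrests the cell cycle, rose by 0.93 log2 (SE 0.09, adjusted p = 3.88e-05). Of 27 measured p53 targets 16 rose, 2 fell and 9 did not pass; adjusted over the list alone 17 rose and 2 fell (mean 0.588 log2, camera adjusted p = 5.69e-09), and adjusted p = 0.00434 with an estimated correlation. Among 23 measured oxidative stress genes 17 rose, 2 fell and 4 did not pass, with the same counts over the list alone, among them the cystine transporter gene Slc7a11 at 3.31 log2 (SE 0.29) and the metallothionein gene Mt2 at 1.12 log2 (SE 0.09). The mean of that list was 0.589 log2 (camera adjusted p = 6.48e-10), with adjusted p = 0.00321 with an estimated correlation. These 3 lists, stress keratins, p53 targets and oxidative stress, were the SPF calls that held with an estimated correlation, out of 23.

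Genes of leukocyte recruitment rose steeply. The neutrophil attractants Cxcl3 and Cxcl1 rose by 3.12 log2 (SE 0.21) and 2.57 log2 (SE 0.15), and the monocyte attractants Ccl7, Ccl2 and Ccl3 by 3.26 log2 (SE 0.20), 3.12 log2 (SE 0.21) and 4.56 log2 (SE 0.41). Of 28 measured chemokines 14 rose, 3 fell and 11 did not pass, the same over the list alone (mean 1.12 log2, camera adjusted p = 9.20e-06; adjusted p = 0.304 with an estimated correlation). Il6 rose by 3.56 log2 (SE 0.29, adjusted p = 1.0e-05) and the prostaglandin synthase gene Ptgs2, a long known mediator of sunburn, by 3.92 log2 (SE 0.17, adjusted p = 1.36e-07). Among 28 neutrophil markers 18 rose, 0 fell and 10 did not pass, the same over the list alone, with Stfa1 at 4.23 log2 (SE 0.32), Trem1 at 2.63 log2 (SE 0.26) and S100a8 at 3.17 log2 (SE 0.36). The neutrophil list had a mean of 1.61 log2 (camera adjusted p = 5.59e-09; adjusted p = 0.194 with an estimated correlation). Of 22 macrophage and monocyte markers 13 rose, 0 fell and 9 did not pass, and over the list alone 13 rose and 1 fell, with the scavenger receptor gene Msr1 at 2.23 log2 (SE 0.31) and Chil3 at 3.15 log2 (SE 0.47). The macrophage list averaged 0.995 log2 (camera adjusted p = 4.71e-05; adjusted p = 0.457 with an estimated correlation).

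Interferon, proliferation and antimicrobial genes also rose in SPF skin. Isg15 rose by 1.47 log2 (SE 0.20) and Zbp1, a sensor of Z-form nucleic acid, by 1.67 log2 (SE 0.28). Of 24 type I interferon genes 15 rose, 0 fell and 9 did not pass, and 21 rose over the list alone (mean 1.04 log2, camera adjusted p = 3.85e-10; adjusted p = 0.304 with an estimated correlation). Among 32 cell cycle genes 29 rose, 0 fell and 3 did not pass, the same over the list alone, with the replication helicase genes Mcm5 and Mcm3 both at 1.07 log2 (SE 0.09 and 0.10). The cell cycle list averaged 0.641 log2 (camera adjusted p = 1.76e-16; adjusted p = 0.194 with an estimated correlation). The defensin gene Defb14 and the iron-withholding lipocalin gene Lcn2 both rose by 2.67 log2 (SE 0.23 and 0.22). Of 25 antimicrobial genes 11 rose, 2 fell and 12 did not pass, and 12 rose over the list alone (mean 0.725 log2, camera adjusted p = 0.000120; adjusted p = 0.194 with an estimated correlation).

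The genes that fell in SPF skin included markers of resident epidermal immunity. Skint9, Skint7 and Skint10, members of a family expressed in keratinocytes and tied to epidermal gamma delta T cells, fell by 2.85 log2 (SE 0.40), 2.67 log2 (SE 0.20) and 2.65 log2 (SE 0.29). The defensin gene Defb8 fell by 3.08 log2 (SE 0.51), and the cytokine receptor genes Il12rb2 and Il20ra fell by 3.07 log2 (SE 0.35) and 2.85 log2 (SE 0.45). T cell receptor complex genes fell too, Cd3e by 1.90 log2 (SE 0.22) and Cd3g by 1.95 log2 (SE 0.23). Of 23 T cell markers 0 rose, 6 fell and 17 did not pass, and over the list alone 1 rose and 6 fell (mean -0.391 log2, camera adjusted p = 0.00313; adjusted p = 0.354 with an estimated correlation). Among 16 clock genes 3 rose, 10 fell and 3 did not pass, the same over the list alone, with the output regulators Dbp at -1.11 log2 (SE 0.17) and Hlf at -1.13 log2 (SE 0.14). The clock list averaged -0.310 log2 (camera adjusted p = 0.0139; adjusted p = 0.194 with an estimated correlation).

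The call of the Langerhans and dendritic cell list and the mean of the hair list depended on single mice in SPF skin. Cd207, the langerin gene of Langerhans cells, fell by 0.95 log2 (SE 0.12, adjusted p = 0.000220). Of 22 measured genes of its list 1 rose, 5 fell and 16 did not pass, the same over the list alone (mean -0.338 log2, camera adjusted p = 0.0290; adjusted p = 0.457 with an estimated correlation). That call ended without SPF UV- replicate 1 (mean -0.294 log2, camera adjusted p = 0.0512) and without SPF UV- replicate 3 (mean -0.315 log2, camera adjusted p = 0.0595), while the mean moved little. The hair keratin list had a mean of 0.786 log2 (31 genes, 3 rose, 2 fell and 26 did not pass; 3 rose and 1 fell over the list alone; camera adjusted p = 0.0106, and adjusted p = 0.631 with an estimated correlation), and without SPF UV+ replicate 1 the mean was 0.213 log2 (adjusted p = 0.244). Mouse 1 of that group had a hair list score of 0.329, against -1.36 and -1.42 in the other 2.

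Some epidermal and inflammatory genes that rose in SPF skin rose in GF skin too, while the stress keratin list as a whole was not called there (camera adjusted p = 0.128). Krt6b rose by 5.74 log2 (SE 0.23, 53.3-fold), Krt16 by 2.96 log2 (SE 0.12, 7.76-fold) and Il1b by 3.66 log2 (SE 0.39, 12.6-fold, adjusted p = 2.28e-05; n = 3 mice per group). The cornified envelope gene Sprr2g rose by 3.90 log2 (SE 0.16), Epgn by 3.58 log2 (SE 0.22), the cysteine protease inhibitor genes Stfa1 and Stfa3 of neutrophils by 3.71 log2 (SE 0.32) and 3.44 log2 (SE 0.21), and Slfn4, an interferon-induced gene of myeloid cells, by 4.29 log2 (SE 0.49). Il6 rose by 2.42 log2 (SE 0.29), Ptgs2 by 3.06 log2 (SE 0.17), Ccl7 by 2.83 log2 (SE 0.20) and Ccl2 by 2.65 log2 (SE 0.21). Of 28 chemokines 13 rose, 0 fell and 15 did not pass, and 16 rose over the list alone (mean 0.828 log2, camera adjusted p = 2.84e-05; adjusted p = 0.295 with an estimated correlation). Of 28 neutrophil markers 13 rose, 1 fell and 14 did not pass, the same over the list alone (mean 1.03 log2, camera adjusted p = 0.000953; adjusted p = 0.348 with an estimated correlation). Of 22 macrophage and monocyte markers 13 rose, 0 fell and 9 did not pass, and 16 rose over the list alone (mean 1.13 log2, camera adjusted p = 2.84e-05; adjusted p = 0.430 with an estimated correlation), and the mean was 0.676 log2 without GF UV+ replicate 2 (camera adjusted p = 0.000181). S100a8 did not pass in GF skin (0.48 log2, SE 0.36, adjusted p = 0.379).

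Among 27 p53 targets in GF skin 19 rose, 2 fell and 6 did not pass, and over the list alone 19 rose and 3 fell. Tnfrsf10b rose by 1.97 log2 (SE 0.11), Eda2r, a death receptor gene, by 1.84 log2 (SE 0.12) and the repair nuclease gene Ercc5 by 0.86 log2 (SE 0.08). Ercc5 also belongs to the nucleotide excision repair list, which was not called (22 genes, 2 rose, 0 fell and 20 did not pass, 1 rose over the list alone; mean 0.042 log2, camera adjusted p = 0.816). The p53 list mean was 0.558 log2 (camera adjusted p = 2.05e-07), and adjusted p = 0.0174 with an estimated correlation made it the only GF list of 22 called that held. Cdkn1a rose by 0.33 log2 (SE 0.09, adjusted p = 0.0210), a call that ended on leaving out any of 3 mice (highest adjusted p = 0.0671). Of 24 type I interferon genes 22 rose, 0 fell and 2 did not pass, the same over the list alone, with Oas2 at 1.75 log2 (SE 0.22) and Stat2 at 1.29 log2 (SE 0.16). The interferon list averaged 1.32 log2 (camera adjusted p = 2.96e-10; adjusted p = 0.289 with an estimated correlation). Among 11 targets of the aryl hydrocarbon receptor, which senses tryptophan photoproducts, 7 rose, 1 fell and 3 did not pass, and 8 rose and 1 fell over the list alone, with Cyp1a1 at 1.73 log2 (SE 0.15) and Aldh3a1 at 1.77 log2 (SE 0.14). The receptor target list averaged 0.805 log2 (camera adjusted p = 0.000256; adjusted p = 0.0809 with an estimated correlation).

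The largest falls in GF skin were all hair genes. Krtap6-5, a keratin-associated protein of the hair shaft, fell by 7.78 log2 (SE 0.60, 220-fold), Krt26 of the inner root sheath by 7.75 log2 (SE 0.70, 216-fold) and Krtap8-1 by 7.66 log2 (SE 0.85, 202-fold). Of 31 genes of the hair list 0 rose, 30 fell and 1 did not pass, and over the list alone 1 rose and 30 fell (mean -4.90 log2, camera adjusted p = 2.46e-31; adjusted p = 0.0809 with an estimated correlation). With them fell 12 of 15 pigmentation genes, with 0 rising and 3 not passing and the same counts over the list alone, among them the melanosome gene Oca2 by 3.61 log2 (SE 0.13) and Tyr, the tyrosinase gene, by 3.47 log2 (SE 0.18). The pigmentation list averaged -1.95 log2 (camera adjusted p = 6.90e-13; adjusted p = 0.0809 with an estimated correlation). Of 32 cell cycle genes 0 rose, 23 fell and 9 did not pass, and 24 fell over the list alone, Kif11 by 1.16 log2 (SE 0.15) and Ube2c by 0.90 log2 (SE 0.11). The cell cycle genes averaged -0.589 log2 (camera adjusted p = 1.44e-11; adjusted p = 0.259 with an estimated correlation). The stress keratin list, with 13 of 28 genes rising, 6 falling and 9 not passing (14 and 8 over the list alone), was not called in GF skin (mean 0.504 log2, camera adjusted p = 0.128).

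Other groups rose in GF skin while the hair list fell. All 22 measured skeletal muscle markers rose, also over the list alone, with Tnnt3 at 1.39 log2 (SE 0.16) and Ckmt2, the mitochondrial creatine kinase gene, at 1.79 log2 (SE 0.19). The muscle list averaged 1.24 log2 (camera adjusted p = 1.16e-13; adjusted p = 0.241 with an estimated correlation). Of 19 endothelial markers 18 rose, 0 fell and 1 did not pass, the same over the list alone, with Pecam1 at 1.16 log2 (SE 0.11) and the leukocyte adhesion gene Sele at 2.04 log2 (SE 0.20). The endothelial list averaged 0.892 log2 (camera adjusted p = 2.65e-10; adjusted p = 0.218 with an estimated correlation). Among 14 basal keratinocyte markers 11 rose, 0 fell and 3 did not pass, the same over the list alone, with the hemidesmosome genes Itgb4 at 1.87 log2 (SE 0.14) and Lamb3 at 1.20 log2 (SE 0.11). The basal keratinocyte list averaged 0.845 log2 (camera adjusted p = 5.59e-07; adjusted p = 0.218 with an estimated correlation).

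**Figure D1:**
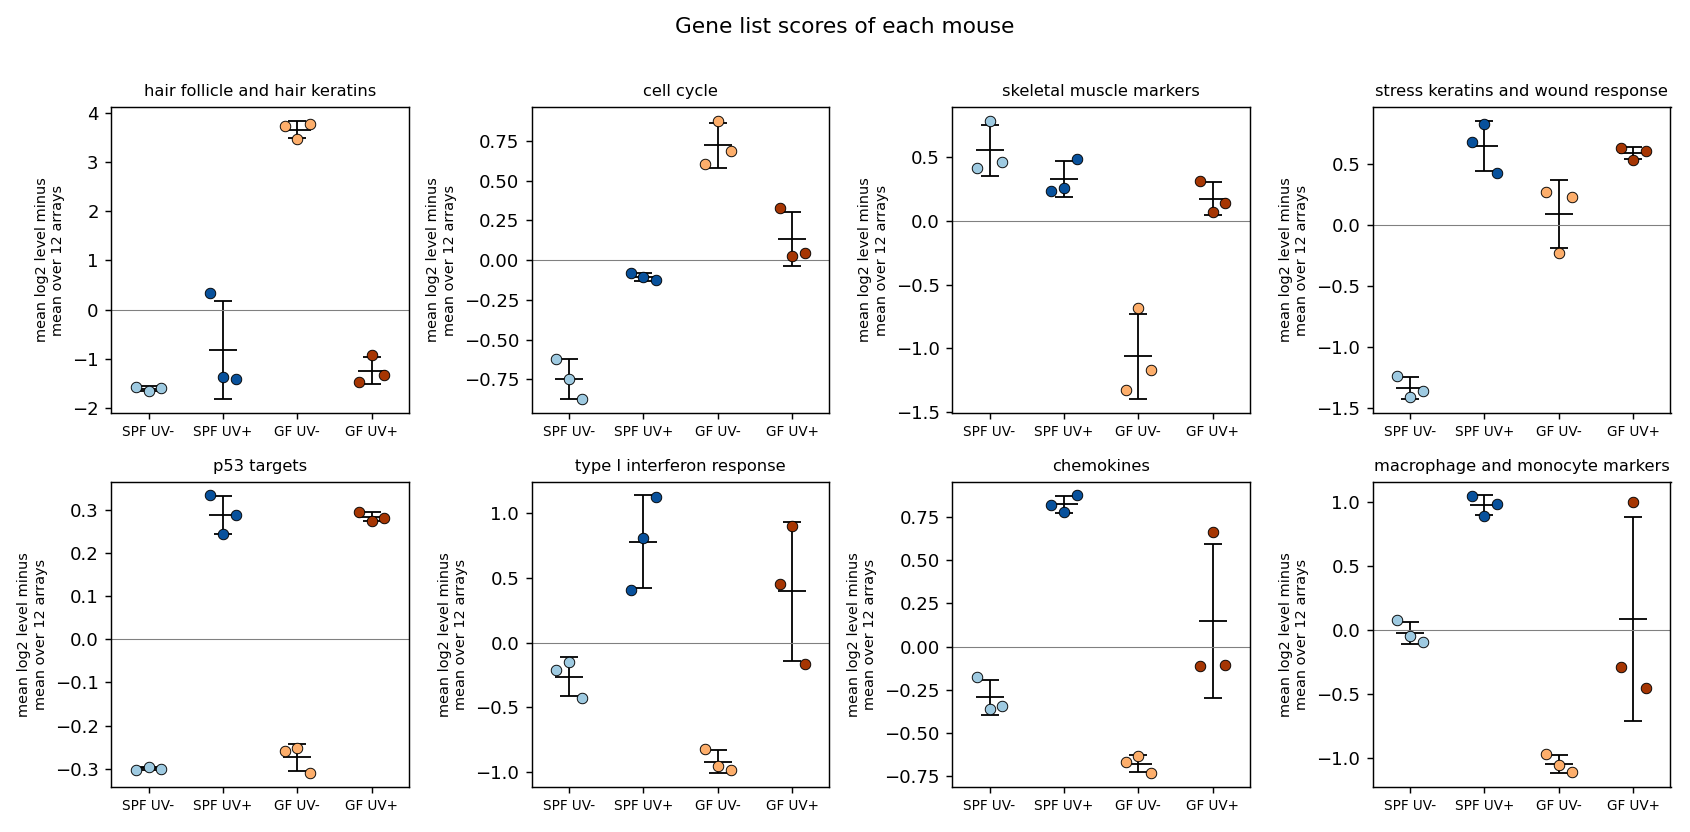
Mean log2 level of the genes of 8 lists in each mouse, minus the mean over all 12 arrays, by group (points, mice; bars, mean and SD of 3 mice). The hair list stood at 3.46 to 3.78 in the unexposed GF skins, and macrophage markers in the exposed GF skins were at -0.290, 1.003 and -0.449.

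The UV responses of the 2 housings overlapped in part. There were 1097 genes that rose in both, against 470.5 for independent lists, and 510 that fell in both, against 265.7. Another 285 rose in SPF and fell in GF skin (303.8 for independent lists), and 385 fell in SPF and rose in GF skin (411.4). Krt6b, Il1b, Epgn and Slfn4 were among the 10 largest rises of both housings. Over all 22180 genes the effects correlated at Pearson r = 0.178 (covariance 0.0514, Spearman rho = 0.211), and no mouse entered both effects. With a jackknife SE of 0.106 over mice this r lies within 2 SE of 0. This r was 0.115 without SPF UV+ replicate 3 and 0.261 without SPF UV+ replicate 1. The level of the unexposed GF skins enters r, rho and the overlap counts through the GF effect. The UV effect in GF skin had a covariance of -0.389 with the GF minus SPF difference without UV, against -0.0103 in simulated unchanged groups. The low r therefore does not show that the responses to UV were unrelated. Over the 7172 genes changed by UV on average, the median change of effect size in GF against SPF skin was 0.08 log2 (exact two-sided p = 0.225 over 400 assignments), and 43.6% of genes had the smaller effect in GF skin. A gene shifted only in the unexposed GF skins counts as a larger GF effect by construction. The median and this share therefore cannot tell a stronger GF response from the different unexposed level. The median had a jackknife SE of 0.07 log2 and was 0.129 log2 without GF UV- replicate 2, 0.128 without GF UV+ replicate 3 and 0.124 without GF UV+ replicate 1. On a single simulated data set for each case this exact test gave p = 0.0850 for a true reduction and p = 0.0700 for none. These runs did not separate the cases. Single runs without a housing difference in unexposed skin cannot show how the test performs here. No conclusion was drawn from its p.

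**Figure D2:**
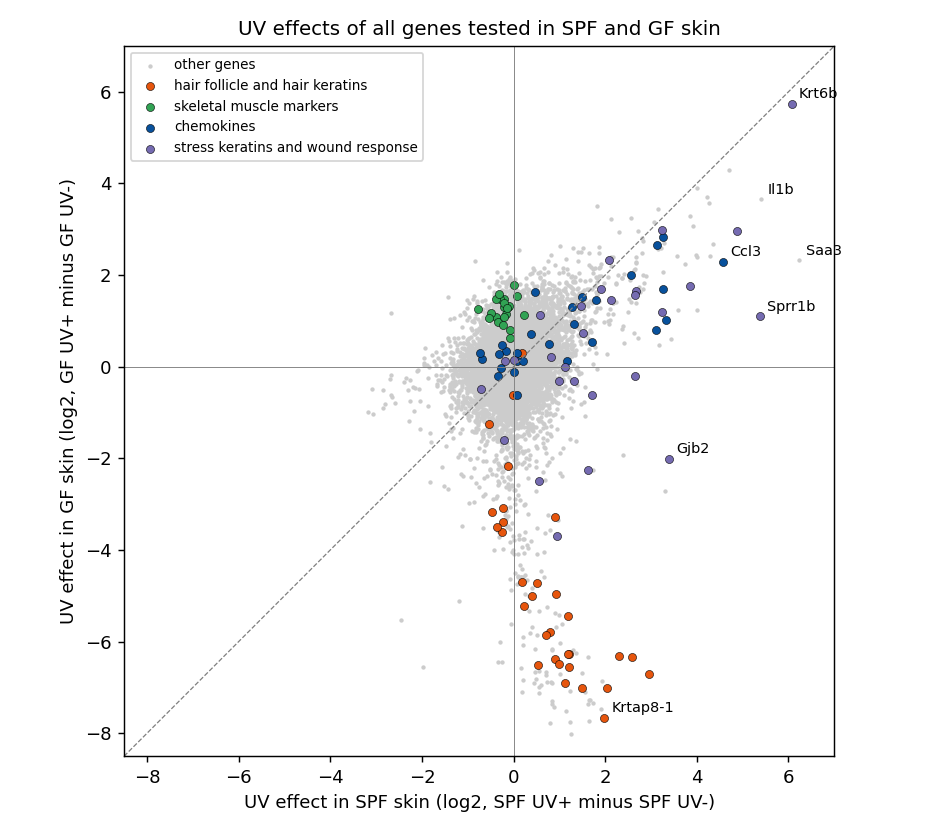
UV effect in GF skin (vertical) against UV effect in SPF skin (horizontal), both in log2, with 1 point per gene and 4 lists in colour. Hair genes lay far below zero in GF skin, with Krtap8-1 at -7.66 log2, and Krt6b lay high in both, at 6.07 and 5.74 log2.

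Without UV, GF skin held far higher levels of hair genes than SPF skin. Krtap4-7 was higher by 8.75 log2 (SE 0.82, 430-fold), Krt71 of the inner root sheath by 8.12 log2 (SE 0.84, 277-fold) and Crym by 4.60 log2 (SE 0.19, 24.3-fold; n = 3 mice per group). Of 31 hair genes 30 were higher, 0 lower and 1 did not pass, the same over the list alone (mean 5.26 log2, camera adjusted p = 8.12e-27; adjusted p = 0.118 with an estimated correlation). The pigment genes Oca2 and Tyr were higher by 3.77 log2 (SE 0.13) and 3.48 log2 (SE 0.18), and 12 of 15 pigmentation genes were higher, 0 lower and 3 not passing (13 higher over the list alone; mean 1.82 log2, camera adjusted p = 6.65e-10; adjusted p = 0.118 with an estimated correlation). All 32 cell cycle genes were higher, also over the list alone, with the mitotic genes Ube2c at 2.01 log2 (SE 0.11) and Plk1 at 1.76 log2 (SE 0.10). The proliferation list averaged 1.47 log2 (camera adjusted p = 4.28e-26; adjusted p = 0.121 with an estimated correlation). The gap junction gene Gjb2 was higher by 5.20 log2 (SE 0.16) and Krt75 by 3.02 log2 (SE 0.13) within the stress keratin list, where 19 of 28 were higher, 0 lower and 9 not passing, the same over the list alone (mean 1.43 log2, camera adjusted p = 1.28e-08; adjusted p = 0.161 with an estimated correlation). Whether transcripts of this list came from epidermis or from hair follicles was not tested, so its higher level does not show a wound state of unexposed GF skin.

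Stroma, vessel and muscle transcripts were lower in unexposed GF skin. The muscle kinase gene Mylk4 was at -3.16 log2 (SE 0.24) against SPF skin, Mstn, whose product limits muscle growth, at -2.79 log2 (SE 0.29) and the fuel switch gene Pdk4 at -2.53 log2 (SE 0.22). All 22 skeletal muscle markers were lower, also over the list alone (mean -1.61 log2, camera adjusted p = 5.31e-14; adjusted p = 0.277 with an estimated correlation), and so were all 19 endothelial markers, Pecam1 at -1.20 log2 (SE 0.11). The endothelial mean was -0.901 log2 (camera adjusted p = 5.17e-09; adjusted p = 0.237 with an estimated correlation). Of 22 dermal matrix genes 1 was higher, 21 were lower and 0 did not pass, the same over the list alone, with the collagen genes Col5a2 at -1.36 log2 (SE 0.12) and Col6a3 at -1.27 log2 (SE 0.11). The dermal matrix mean was -0.887 log2 (camera adjusted p = 5.90e-08; adjusted p = 0.319 with an estimated correlation). Among 16 clock genes 2 were higher, 11 lower and 3 not passing (2 and 12 over the list alone), with Nr1d1 at -1.78 log2 (SE 0.16). The clock gene mean was -0.628 log2 (camera adjusted p = 0.000747; adjusted p = 0.118 with an estimated correlation).

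Some immune lists were lower in unexposed GF skin as well, and others were not called. Lower levels were not particular to immune genes: 18 of 33 lists were called lower here, the muscle, endothelial and dermal matrix lists among them. The T cell, microbial sensing and interferon means were smaller in size than the means of those lists. The macrophage mean was larger in size than the endothelial and dermal matrix means and smaller than that of muscle. Of 22 macrophage and monocyte markers 0 were higher, 14 lower and 8 not passing, and 20 lower over the list alone, with the scavenger receptor gene Cd163 at -1.35 log2 (SE 0.24). The macrophage mean was -1.03 log2 (camera adjusted p = 0.000107; adjusted p = 0.484 with an estimated correlation). Among 23 T cell markers 0 were higher, 13 lower and 10 not passing, the same over the list alone, with Cd3g at -1.80 log2 (SE 0.23). The T cell mean was -0.607 log2 (camera adjusted p = 0.000470; adjusted p = 0.311 with an estimated correlation). Of 35 microbial sensing genes 0 were higher, 17 lower and 18 not passing, the same over the list alone, among them the flagellin receptor gene Tlr5 at -1.12 log2 (SE 0.16) and the peptidoglycan sensor gene Nod2 at -0.85 log2 (SE 0.14). The microbial sensing mean was -0.495 log2 (camera adjusted p = 0.000478; adjusted p = 0.384 with an estimated correlation). Tlr2, a lipoprotein receptor gene, was lower, at -0.61 log2 (SE 0.21, adjusted p = 0.0385), a call that ended on leaving out any of 6 mice (highest adjusted p = 0.105). Of 24 type I interferon genes 0 were higher, 12 lower and 12 not passing, and 14 lower over the list alone (mean -0.657 log2, camera adjusted p = 0.00256; adjusted p = 0.508 with an estimated correlation). Il1b (-0.17 log2, SE 0.39, adjusted p = 0.781) and Il6 (-0.07 log2, SE 0.29, adjusted p = 0.894) did not pass without UV. Not called were neutrophil markers (28 genes, 3 higher, 4 lower and 21 not passing, 2 and 3 over the list alone; mean -0.093 log2, camera adjusted p = 0.972) and antimicrobial genes (25 genes, 3 higher, 7 lower and 15 not passing, the same over the list alone; mean -0.023 log2, camera adjusted p = 0.757). Nor were proinflammatory cytokines called (21 genes, 0 higher, 5 lower and 16 not passing, 4 lower over the list alone; mean -0.198 log2, camera adjusted p = 0.349). None of the 25 lists called without UV held with an estimated correlation.

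The UV response differed between GF and SPF skin for 4889 genes, with the effect more positive in GF skin for 2795 and more negative for 2094. With each array's median subtracted these were 2394 and 2379, so the uneven split depended on scaling. Hair genes led: the GF minus SPF effect was -9.67 log2 (SE 1.19) for Krt71 and -4.88 log2 (SE 0.26) for Crym, and of 31 hair genes 29 had a more negative effect in GF skin, 0 a more positive one and 2 did not pass (30 over the list alone; mean -5.68 log2, camera adjusted p = 3.70e-33; adjusted p = 0.0952 with an estimated correlation). All 32 cell cycle genes had a more negative effect, also over the list alone, Mcm5 by -1.38 log2 (SE 0.13). The cell cycle mean was -1.23 log2 (camera adjusted p = 5.68e-26; adjusted p = 0.115 with an estimated correlation). All 22 muscle markers had a more positive effect, also over the list alone, Ryr1, the calcium release channel gene, by 1.90 log2 (SE 0.27). The muscle mean was 1.46 log2 (camera adjusted p = 5.21e-14; adjusted p = 0.304 with an estimated correlation). Among 28 stress keratin genes 15 had a more negative effect, 0 a more positive one and 13 did not pass (18 and 1 over the list alone), with Gjb2 at -5.41 log2 (SE 0.22) and Krt6a at -1.08 log2 (SE 0.25). The stress keratin mean was -1.49 log2 (camera adjusted p = 6.53e-10; adjusted p = 0.115 with an estimated correlation). None of the 17 lists called here held with an estimated correlation.

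Most of these differences lay in the unexposed skins. Of the 4889 genes 4646 (95.0%) also differed between GF and SPF skin without UV with the matching sign, 20 differed after UV and 231 in neither state. The numbers 20 and 231 rest on the 26 calls after UV, a count that was 1444 without GF UV+ replicate 2. The difference of effects and the comparison without UV used the same 6 unexposed mice, so some likeness was built in. Their effects correlated at -0.951 (covariance -0.496), against -0.704 (covariance -0.0205) in simulated unchanged groups, where at most 1 gene was called in both. Krt16 illustrates the pattern: its mean level was 6.09 and 8.09 log2 in unexposed SPF and GF skin, and 10.96 and 11.05 log2 after UV.

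Single inflammatory genes had a weaker UV response in GF skin, while most immune lists were not called for the difference of effects. Cxcl3 and Cxcl2 had GF minus SPF effects of -2.31 log2 (SE 0.30, adjusted p = 0.000222) and -2.30 log2 (SE 0.36, adjusted p = 0.000674), Nlrp3, an inflammasome gene, -2.09 log2 (SE 0.36, adjusted p = 0.00128) and Trem1, an amplifier of myeloid inflammation, -1.89 log2 (SE 0.36, adjusted p = 0.00250). Cxcl3 stood at 2.49 and 2.31 log2 in unexposed SPF and GF skin and at 5.61 and 3.12 log2 after UV. All but the level in exposed SPF skin were at or below the highest level of Xist (3.21 log2), hardly expressed in males, so its difference of effects has no exact size and its difference after UV is a lower bound. S100a8 had an effect of -2.69 log2 (SE 0.51, adjusted p = 0.00238), with a level higher in GF skin without UV by 1.30 log2 (SE 0.36, adjusted p = 0.0125). For Il1b the effect was -1.73 log2 (SE 0.56, adjusted p = 0.0429), and the call ended on leaving out any of 9 mice (highest adjusted p = 0.0968). Il6 (-1.14 log2, SE 0.41, adjusted p = 0.0695) and S100a9 (-1.16 log2, SE 0.43, adjusted p = 0.0755) did not pass. Of 28 chemokines 6 had a more positive effect, 4 a more negative one and 18 did not pass (6 and 5 over the list alone), and the list was not called (mean -0.290 log2, camera adjusted p = 0.419). Nor was the macrophage list (mean 0.139 log2, 0 of 22 passing over all genes or over the list alone, camera adjusted p = 0.785), but without GF UV+ replicate 2 it was called with a mean of -0.319 log2 (camera adjusted p = 0.00720). Of 35 microbial sensing genes, Nlrp3 among them, 5 had a more positive effect, 1 a more negative one and 29 did not pass, the same over the list alone (mean -0.022 log2, median 0.180 log2, camera direction up, adjusted p = 0.557). Of 21 proinflammatory cytokines 1 was more positive, 2 more negative and 18 did not pass (1 and 0 over the list alone; mean -0.146 log2, camera adjusted p = 0.469). Of 30 immune regulation genes 6 were more positive, 1 more negative and 23 did not pass, the same over the list alone (mean 0.313 log2, camera adjusted p = 0.0676). The neutrophil list had a mean of -0.581 log2 (camera adjusted p = 0.0196, and adjusted p = 0.594 with an estimated correlation). Of its 28 genes 1 was more positive, 4 were more negative and 23 did not pass, the same over the list alone. Its call ended without GF UV+ replicate 1 (mean -0.438 log2, camera adjusted p = 0.0619) or GF UV+ replicate 3 (mean -0.463 log2, camera adjusted p = 0.0632). With only genes at or above the median brightness the mean was -0.31 log2 (camera adjusted p = 0.415).

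After UV, 8 genes were higher and 18 lower in GF than in SPF skin. This split depended on the setting: 22 and 18 with an intensity trend and robust prior, 15 and 13 with bright genes alone, and 1 and 0 with only the 2 groups compared. Cxcl3 and Cxcl2, which attract neutrophils, were at -2.48 log2 (SE 0.21, adjusted p = 0.000778) and -2.33 log2 (SE 0.25, adjusted p = 0.00632) against SPF skin, and the monocyte attractant Ccl3 was at -2.49 log2 (SE 0.41, adjusted p = 0.0486; n = 3 mice per group). Lower too were Acod1, the itaconate synthase gene of activated macrophages, at -2.39 log2 (SE 0.39, adjusted p = 0.0486) and Nlrp3 at -1.90 log2 (SE 0.25, adjusted p = 0.0258). So were Trem1 at -1.87 log2 (SE 0.26, adjusted p = 0.0258) and the lipopolysaccharide receptor gene Cd14 at -1.72 log2 (SE 0.27, adjusted p = 0.0486). The kallikrein gene Klk1 was at -2.31 log2 (SE 0.31, adjusted p = 0.0258) and the antiproteinase gene Wfdc12 at -1.41 log2 (SE 0.21, adjusted p = 0.0486). Serpina3j, a serine protease inhibitor gene, was higher by 2.48 log2 (SE 0.34, adjusted p = 0.0258). Serpinb13 of keratinocytes was higher by 0.80 log2 (SE 0.12, adjusted p = 0.0486) and Il22ra1, the epithelial interleukin 22 receptor gene, by 0.47 log2 (SE 0.08, adjusted p = 0.0486). Cxcl3 kept its call whichever mouse was left out, and Cxcl2 lost it without SPF UV+ replicate 2 (adjusted p = 0.0662). Both lost it with only the 2 groups compared (adjusted p = 0.0723 and 0.294). The other calls ended on leaving out any of 7 mice for Klk1 (highest adjusted p = 0.156) and Serpina3j (0.113), 8 for Trem1 (0.182), 9 for Nlrp3 (0.156), 10 for Wfdc12 (0.278) and Serpinb13 (0.278), and 11 for Ccl3 (0.281), Acod1 (0.278), Cd14 (0.278) and Il22ra1 (0.278).

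By camera at the preset correlation, lists of inflammatory genes were lower after UV too, with few genes passing alone. None of the calls in this paragraph held with fry for direction. Of 10 splits of these mice 4, the real one included, gave at least as many called lists, up to 22 against the real 19. The camera p values therefore do not measure the spread over mice. Of 22 macrophage and monocyte markers 0 were higher, 0 lower and 22 not passing over all genes, and 17 were lower over the list alone (mean -0.888 log2, camera adjusted p = 1.24e-15; adjusted p = 0.252 with an estimated correlation; mean -1.35 log2 without GF UV+ replicate 2). Of 28 chemokines 3 were lower, 0 higher and 25 not passing, and 11 lower over the list alone (mean -0.675 log2, camera adjusted p = 2.48e-10; adjusted p = 0.252 with an estimated correlation). Among 28 neutrophil markers 1 was lower, 0 higher and 27 not passing, and over the list alone 13 were lower and 1 higher (mean -0.674 log2, camera adjusted p = 1.24e-08; adjusted p = 0.252 with an estimated correlation). Of 35 microbial sensing genes 2 were lower, 0 higher and 33 not passing, and 16 were lower and 1 higher over the list alone (mean -0.517 log2, camera adjusted p = 1.47e-10; adjusted p = 0.252 with an estimated correlation). Il1b (-1.90 log2, SE 0.39, adjusted p = 0.109), Il6 (-1.20 log2, SE 0.29, adjusted p = 0.159) and S100a8 (-1.40 log2, SE 0.36, adjusted p = 0.169) did not pass.

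Lists of other cell types were also called by camera at the preset correlation after UV, and none of those below held with fry for direction. Of 22 dermal matrix and fibroblast markers 0 passed over all genes and 15 were lower over the list alone (mean -0.426 log2, camera adjusted p = 4.40e-11; adjusted p = 0.266 with an estimated correlation; mean -0.271 log2 without GF UV+ replicate 1). Of 19 endothelial markers 0 passed and 3 were lower over the list alone (mean -0.234 log2, camera adjusted p = 1.90e-05; adjusted p = 0.285 with an estimated correlation). The endothelial mean was -0.146 log2 without GF UV+ replicate 1 and -0.137 log2 without SPF UV+ replicate 3. Higher in GF skin were basal keratinocyte markers, with 0 of 14 passing and 8 higher over the list alone (mean 0.296 log2, camera adjusted p = 3.21e-06; adjusted p = 0.252 with an estimated correlation). So were cell cycle genes, with 0 of 32 passing and 2 higher over the list alone (mean 0.238 log2, camera adjusted p = 1.20e-09; adjusted p = 0.285 with an estimated correlation; mean 0.141 log2 without GF UV+ replicate 1). None of the 19 lists called after UV held with an estimated correlation.

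The p53 and stress keratin lists were not called after UV, which does not show that levels were equal. The p53 list had a mean of -0.004 log2 after UV (median 0.006 log2, camera direction up) with 0 of 27 genes passing over all genes or over the list alone (camera adjusted p = 0.996), while fry for mixed directions called the list (adjusted p = 0.0171). For the stress keratin list the mean was -0.055 log2 with 0 of 28 passing either way (camera adjusted p = 0.798). Cdkn1a differed by 0.07 log2 (SE 0.09, adjusted p = 0.845) and Krt6a by 0.18 log2 (SE 0.18, adjusted p = 0.756). The hair list was not called after UV (mean -0.422 log2, 0 of 31 passing, camera adjusted p = 0.0685); without SPF UV+ replicate 1 its mean was 0.152 log2 (adjusted p = 0.0176).

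The exposed GF mice were not alike. Macrophage markers in GF UV+ replicate 2 scored 1.003, near the 0.893 to 1.05 of the SPF UV+ mice, while replicates 1 and 3 scored -0.290 and -0.449. Leaving this mouse out raised the number of genes that differed after UV from 26 to 1444, with 574 higher and 870 lower in GF skin and all 26 among them. Leaving out any other mouse gave 2 to 12. Without it the macrophage mean was -1.35 log2 and the chemokine mean -0.932 log2. Ccl3 was at -3.14 log2 (adjusted p = 2.56e-05), Cxcl3 at -2.78 log2 (adjusted p = 1.52e-05) and Il1b at -2.42 log2 (adjusted p = 0.000709).

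**Figure D3:**
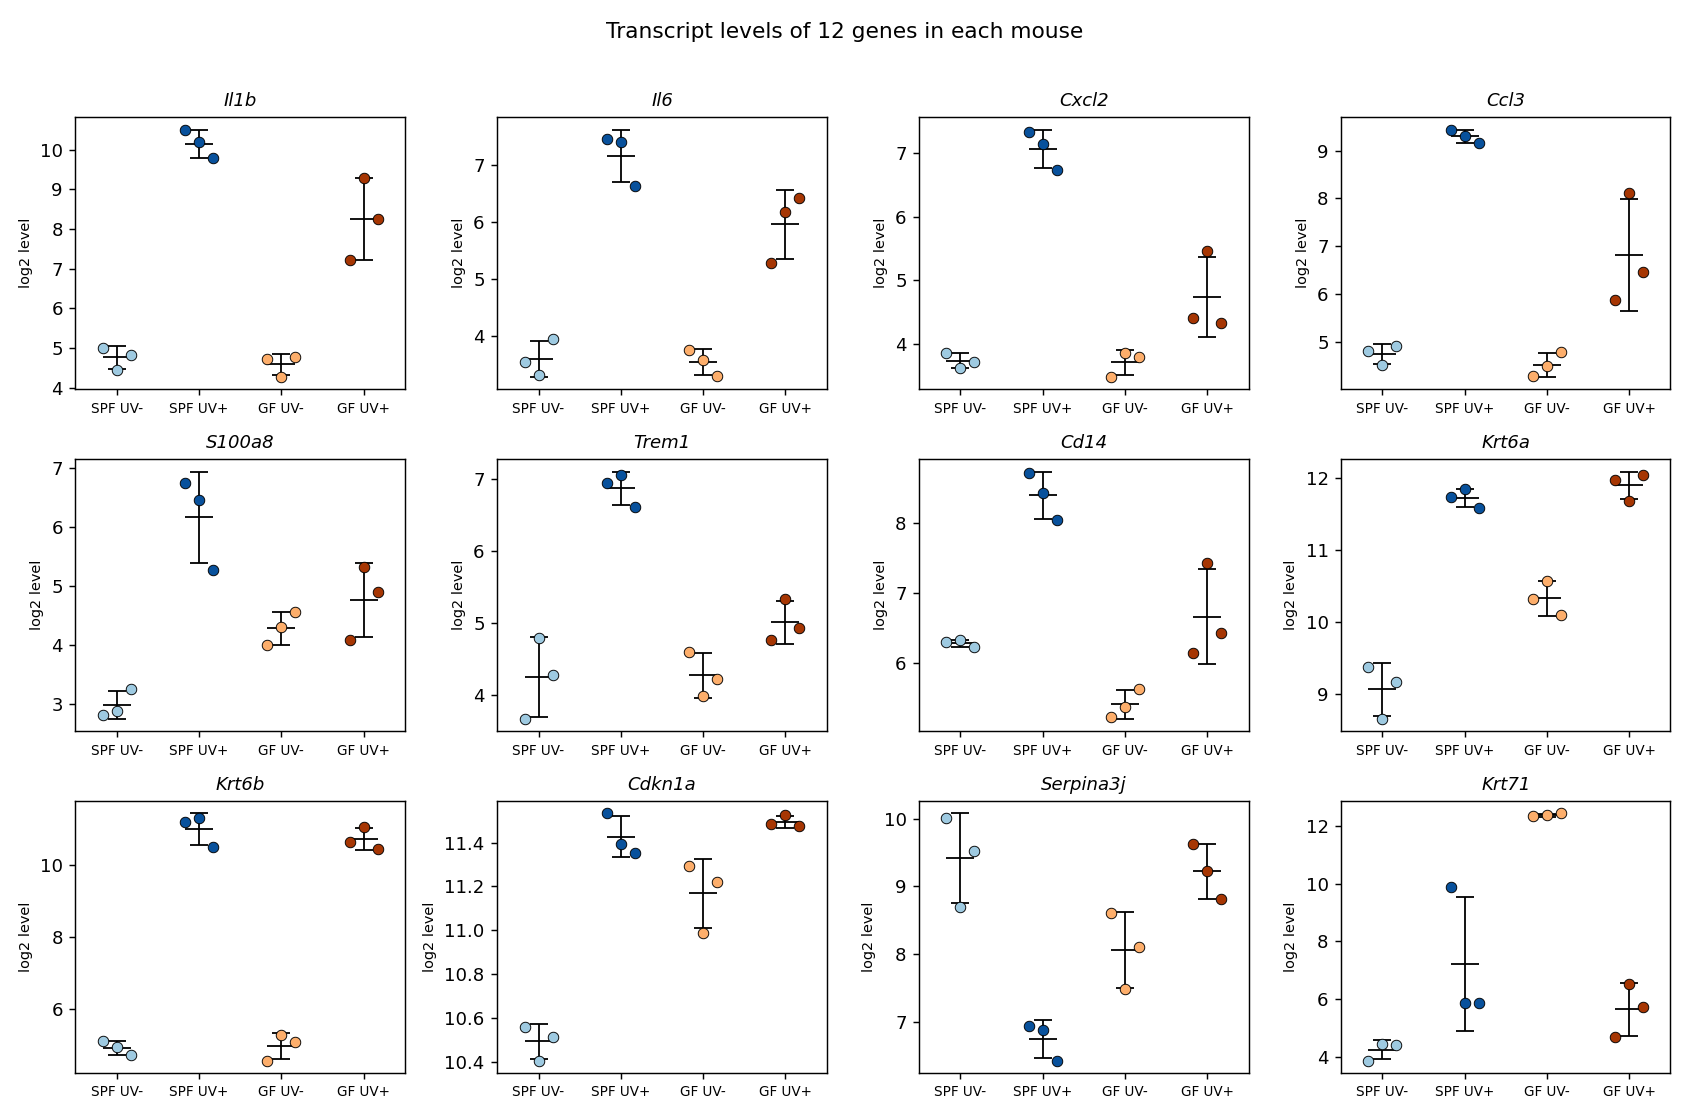
Log2 level of 12 genes in each mouse by group (points, mice; bars, mean and SD of 3 mice). Cxcl2 and Ccl3 reached lower levels in GF than in SPF skin after UV, and Krt71 was at 12.37 log2 in unexposed GF skin against 4.25 log2 in unexposed SPF skin.

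In both UV states 277 genes were lower in GF skin (called without UV and at unadjusted p below 0.01 after UV), against 102 for independent lists, and 139 were higher, against 81.1. Over all 22180 genes, called or not, the 3 exposed and 3 unexposed mice did not overlap for 41.4% in SPF and 40.0% in GF skin. GF and SPF mice did not overlap for 48.5% without UV and 15.7% after UV; chance gives 10%. Of the genes named, S100a8, Defb14, Cxcl3, Sprr2g, Krtap6-5, Krt26, Krtap4-7, Krtap4-2 and Krtap19-5 had a group mean at or below 3.21 log2, the highest level of Xist, a measure of background chosen after its values were seen. Their differences from such a group are lower bounds. With 3 mice per group and 1 array each, precision was limited, and an exact test of 3 against 3 mice cannot give p below 0.100. Sex, age, strain, UV dose and time of sampling were not given in the sources used here, and the sample records state germ-free breeding for all mice, those named SPF included, so the SPF name was taken from the group labels.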

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

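In this part the test of germ-free housing whatever the UV state and the test of a weaker response of the whole skin were chosen after their results were seen, and GF UV+ replicate 2 was singled out after its values were seen. An earlier bound of the housing test had left it undecided. Earlier forms of the whole skin test used levels after UV and included stress keratins, whose higher unexposed level in GF skin made them void, and were replaced by the responses of p53 targets. The unexposed level enters these responses as well.

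The results here were picked out because the UV response differed between GF and SPF skin in a direct test of the difference, which was more positive in GF skin for 2795 genes and more negative for 2094 (2394 and 2379 with each array's median subtracted). Of these 4889 genes 95.0% also differed between GF and SPF skin without UV, so an effect listed here need not lie in exposed skin. Of 100 splits 7 gave as many genes and 31 as many lists, the real one included each time. Among list means of the GF minus SPF effect, the hair list stood at -5.68 log2, pigmentation at -1.86, stress keratins at -1.49, cell cycle at -1.23, oxidative stress at -0.733, neutrophil markers at -0.581, sterol and fatty acid synthesis at -0.191 and nucleotide excision repair at -0.164. More positive in GF skin were skeletal muscle at 1.46 log2, basal keratinocytes at 0.893, endothelium at 0.667, sebaceous gland at 0.629, clock genes at 0.615, T cells at 0.605, Langerhans and dendritic cells at 0.530, adipocytes at 0.474 and dermal matrix at 0.460. None of these 17 lists was called with an estimated correlation (0 lists). Calls that ended without a mouse were sterol synthesis (4 mice, adjusted p up to 0.0658), nucleotide excision repair (0.0672 and 0.0592), dermal matrix (0.0656, mean 0.286 log2 without GF UV+ replicate 2), adipocytes (0.0524), Langerhans cells (0.0576) and neutrophil markers (0.0619 and 0.0632).

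Genes with the most positive GF minus SPF effect were Serpina3j (3.83 log2), the muscle genes Mylk4 (3.17), Mstn (2.96), Defb8 (2.60), Fgf18 (2.57), Skint6 (2.50), Chat (2.48), Mrgprb3 (2.44), the itch receptor gene Il31ra (2.42) and Cyp2e1 (2.42). Those with the most negative effect were the hair genes Krt71 (-9.67 log2), Krtap8-1 (-9.64), Krtap4-7 (-9.39), Krtap4-8 (-9.39), Krt27 (-9.06), Krt26 (-8.99), Krtap19-5 (-8.95), Krtap4-2 (-8.92), Tchh (-8.90) and Krtap4-16 (-8.79). For Krtap4-7, Krt26, Krtap19-5 and Krtap4-2 unexposed SPF skin was at or below the highest level of Xist (3.21 log2), so their effects are lower bounds in size and the order is not exact. Exposed SPF skin enters the effects of hair genes too, and there SPF UV+ replicate 1 stood apart. It had Krt71 at 9.885 log2, against 5.873 and 5.854 log2 in the other SPF UV+ mice. Its hair list score was 0.329, against -1.363 and -1.418. Of the genes fixed in advance, Il20rb (1.53 log2) and Il20ra (1.96) had a more positive effect, and Il1b (-1.73), S100a8 (-2.69), Krt6a (-1.08) and Cdkn1a (-0.60) a more negative one. The calls ended on leaving out any of 9 mice for Il1b (highest adjusted p = 0.0968), 8 for Il20ra (0.0974) and 5 for Defb8 (0.0538).

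Among list members, the GF minus SPF effect was -1.38 log2 for Mcm5, -1.68 for Ube2c, -5.41 for Gjb2, -3.04 for Krt75, -6.02 for Slc7a11, -1.54 for the glutathione reductase gene Gsr, -3.86 for Oca2, -2.46 for Mlana, -4.88 for Crym and -3.13 for Krt32. It was 1.53 log2 for Lamb3, 1.93 for Krt15, 1.495 for Acsbg1, 1.32 for Fa2h, 1.42 for Eno3, 1.90 for Ryr1, 1.10 for Pecam1, 1.12 for Tie1, 0.93 for Cry2 and 1.41 for Nr1d2.

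The 1st pattern is that the unexposed GF skins stood apart from the other 3 groups. Hair follicles in their growth phase fit: a separate set of 17 growth phase regulators, 12 of them higher and 1 lower without UV, had a median at least 1.05 log2 above both SPF UV- and GF UV+ skin. Against more follicles of the same stage, 8 markers of the permanent follicle had a median of -0.375 log2 (SE 0.07, 1 higher and 4 lower). Against housing whatever the UV state, the hair list median was -0.45 log2 after UV (SE 0.596) against 5.91 without UV (SE 0.102). An effect of housing on unexposed skin alone, the age or cohort of these mice, and a stop of hair growth by UV in GF skin stay open and were not tested.

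The 2nd pattern is the lower level of chemokine and myeloid transcripts in GF than in SPF skin after UV. A weaker response of the whole skin cannot be told apart from a weaker immune response: over 20 p53 targets 0.966% of the SPF response was missing in GF skin (SE 5.23) against 33.97% over 14 chemokines (SE 14.1), but p53 targets went both ways, with a mean GF minus SPF effect of -0.008 log2 and an SD of 0.743 over genes where the chemokine share needs -0.291. These responses subtract the unexposed level of the same housing, so the different level of unexposed GF skin enters both shares and the SD. Cdkn1a had a GF minus SPF effect of -0.605 log2 but differed by 0.068 log2 after UV. The p53 list as a whole was not called after UV. No conclusion was drawn from these shares. Less leukocyte RNA fit, with 13 measured pan-leukocyte genes outside the lists at a median of -0.623 log2, but the SE over mice was large at 0.398, and the same genes were lower without UV, at -1.01 log2. GF UV+ replicate 2 lay at a median position of 0.129 between the SPF UV+ mice (0) and the other GF UV+ mice (1). This was over 1444 genes chosen without it (0.139 outside the immune lists). For the other mice the genes were chosen anew, each time without the mouse placed and without replicate 2. Left-out SPF UV+ mice then lay at 0.026, 0.214 and -0.019. GF UV+ replicates 1 and 3, each set against the other alone, lay at 0.861 and 0.865. A wrong label of replicate 2 therefore fits, with 88.8% of the 1444 genes under 0.5. That no SPF UV+ mouse lay near the GF end argues against an exchange of labels between replicate 2 and an SPF UV+ mouse. A GF mouse with a stronger inflammatory response was not tested apart from a wrong label and stays open. The housing difference after UV depends on which holds.

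The 3rd pattern is the set of genes that differed between GF and SPF skin in both UV states, 277 lower and 139 higher. Against unequal sexes, Xist had a range of 0.414 log2 over all 12 arrays. A substrain difference cannot be told apart from housing here, because 3 of 5 marker genes were measured and the largest shared difference was that of Mmrn1, at -1.10 log2 without and -0.719 log2 after UV, short of the 1 log2 set in advance for both states. Nnt differed by -0.966 log2 without and -0.019 log2 after UV, and Wdfy1 by 0.295 and -0.064 log2.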

How the results depend on the processing

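The setting without the GF UV- group was added after seeing the data. With a 2-fold threshold as well, the counts were 686 for UV in SPF skin, 1477 for UV in GF skin, 716 for both housings, 1584 for the difference of effects, 1939 without UV and 14 after UV, fewer by construction. All other counts except that after UV stayed within 1.5 times, with leave-one-out ranges of 3961 to 5638, 4927 to 6177, 6193 to 7383, 4088 to 4961 and 7359 to 8634 in that order. The 26 genes after UV became 40 with an intensity trend and robust prior, 1 with only the 2 groups compared, 9 with quantile normalization, 8 with the mean of probe sets, 4 with all probe sets, 602 with array weights (lowest for GF UV- replicate 2, 0.477, and GF UV+ replicate 2, 0.520), 2 without the GF UV- group and 2 to 1444 in leave-one-out. Fewer arrays or more tests explain part of the falls by construction, and for the rest the cause was not tested.

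List calls with an estimated correlation were 3 for UV in SPF skin, 1 in GF skin and 0 for the difference of effects, without UV and after UV; fry called 30 of mixed direction for the difference of effects and 1 by direction after UV, that of oxidative stress (adjusted p = 0.00808). In 2 lists the direction reversed: macrophage markers in the difference of effects (0.139 log2, leave-one-out -0.319 to 0.407, lowest without GF UV+ replicate 2) and hair genes after UV (-0.422 log2, leave-one-out -0.722 to 0.152, highest without SPF UV+ replicate 1). The cause was not tested. With dim genes left out, calls ended for antimicrobial, aryl hydrocarbon receptor, matrix remodelling and hair lists in SPF skin, antimicrobial and clock lists in GF skin, neutrophil and sterol lists in the difference of effects, chemokine, matrix remodelling and mast cell lists without UV and the Langerhans cell list after UV.

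Of the alternatives for named genes, 2987 of 3074 kept direction and side of the threshold for UV in SPF skin, 2880 of 2921 in GF skin, 2798 of 2875 for the difference of effects, 3069 of 3094 without UV and 2608 of 2928 after UV. Genes that were not called and stayed so count as kept, so these shares do not measure how firm the calls were. After UV, 210 alternatives ended a call and 110 made one. For lists the numbers kept were 658 of 724, 643 of 691, 628 of 691, 644 of 691 and 654 of 724. The number of arrays and the signal over background of dim probe sets limit precision.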

Other observations

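The chance splits reported in this part were chosen before their results were seen, and the genes named follow the same rule as in the report.

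Immediate early genes, which answer stress and growth signals, rose with UV in both housings (n = 3 mice per group). In SPF skin 18 of 21 rose, 1 fell and 2 did not pass, the same over the list alone, with Junb at 1.71 log2 (SE 0.14) and Ier3 at 1.62 log2 (SE 0.12). The SPF mean was 0.809 log2 (camera adjusted p = 1.38e-11; adjusted p = 0.0726 with an estimated correlation). In GF skin 14 rose, 2 fell and 5 did not pass, the same over the list alone, with the nuclear receptor gene Nr4a1 at 1.94 log2 (SE 0.17) and Fosb at 2.31 log2 (SE 0.21). The GF mean was 0.727 log2 (camera adjusted p = 2.84e-05; adjusted p = 0.239 with an estimated correlation). Matrix remodelling genes rose too: in SPF skin 13 of 26 rose, 2 fell and 11 did not pass (13 and 5 over the list alone), with the protease inhibitor gene Timp1 at 2.81 log2 (SE 0.23) and tenascin, Tnc, at 2.67 log2 (SE 0.25). The remodelling list averaged 0.730 log2 (camera adjusted p = 0.000301; adjusted p = 0.354 with an estimated correlation). In GF skin 17 rose, 0 fell and 9 did not pass (17 and 1 over the list alone), with Timp1 at 2.48 log2 (SE 0.23) and the hyaluronan synthase gene Has1 at 1.48 log2 (SE 0.15). In GF skin it averaged 0.859 log2 (camera adjusted p = 7.23e-06; adjusted p = 0.259 with an estimated correlation).

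Single epidermal lipid and barrier genes changed with UV, while the barrier list was not called in either housing. In SPF skin the barrier gene Flg2 fell by 2.16 log2 (SE 0.32, adjusted p = 0.000540) and Dsg1a, a desmosome gene, by 1.02 log2 (SE 0.16), with no call of that list (32 genes, 3 rose, 9 fell and 20 did not pass, 4 and 9 over the list alone; mean -0.195 log2, camera adjusted p = 0.144). In GF skin the lipoxygenase genes Alox12b and Aloxe3, needed for the water barrier, rose by 2.10 log2 (SE 0.16) and 1.52 log2 (SE 0.13), and Tgm3, a transglutaminase gene of hair and epidermis, fell by 3.89 log2 (SE 0.27). There 11 of the 32 barrier genes rose, 7 fell and 14 did not pass, the same over the list alone (mean 0.125 log2, camera adjusted p = 0.560). The lipid gene Elovl3 of sebaceous cells rose in both, by 1.63 log2 (SE 0.10) in SPF and 1.39 log2 (SE 0.10) in GF skin, and Sqle, of sterol synthesis, rose in SPF skin by 0.71 log2 (SE 0.08). The sebaceous list was not called in SPF skin (14 genes, 7 rose, 4 fell and 3 did not pass, 8 and 4 over the list alone; mean 0.294 log2, camera adjusted p = 0.0544). In GF skin 10 rose, 1 fell and 3 did not pass, 11 and 1 over the list alone (mean 0.924 log2, camera adjusted p = 1.37e-05; adjusted p = 0.218 with an estimated correlation). Of 18 sterol and fatty acid genes 8 rose, 0 fell and 10 did not pass in SPF skin, and 11 rose over the list alone (mean 0.251 log2, camera adjusted p = 0.000120; adjusted p = 0.194 with an estimated correlation). In GF skin 6 rose, 4 fell and 8 did not pass (7 and 4 over the list alone), and the sterol list was not called (mean 0.059 log2, camera adjusted p = 0.780).

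Kit, of mast cells and melanocytes, was higher by 1.20 log2 (SE 0.17) in unexposed GF than SPF skin and fell with UV in GF skin by 1.72 log2 (SE 0.17), against the direction of other members of the mast cell list. Of its 14 genes 1 was higher, 7 were lower and 6 did not pass without UV, the same over the list alone (mean -0.484 log2, camera adjusted p = 0.0405; adjusted p = 0.489 with an estimated correlation). That call ended without GF UV- replicate 2 (adjusted p = 0.0662) or SPF UV- replicate 2 (adjusted p = 0.0560). With UV in GF skin 4 rose, 1 fell and 9 did not pass, and the list was not called (mean 0.302 log2, camera adjusted p = 0.129).

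With 3 against 3 mice there are 10 splits, too few for a share under 0.05. The real grouping gave 5230 genes for UV in SPF skin, 6155 in GF skin and 8441 without UV, where the highest other split gave 0 each time, and 26 after UV, where it gave 3; as many genes came in 1 split, the real one, in each case. For lists the real values and the highest others were 23 and 22 (1 split with as many) for UV in SPF skin, 22 and 22 (3 splits) in GF skin, 25 and 18 (1 split) without UV and 19 and 22 (4 splits) after UV. For the mean UV effect 1 of 100 splits, the real one, gave as many as 7172 genes. The highest other, 4889, exchanged the UV labels of a whole housing and so repeats the difference of UV effects. The highest split that mixed exposed with unexposed mice gave 2282.

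For the difference of UV effects 7 of 100 splits gave as many as the real 4889 genes, up to 7023, and 31 of 100 gave as many as 17 lists, up to 24. All 7, the real one included, were among the 12 splits that kept both unexposed groups whole, and splits that mixed these groups gave at most 1 gene. Counts of this size thus came only with the unexposed groups intact, and also where the exposed mice were mixed.

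Within groups, arrays correlated at 0.988 to 0.992 (12 pairs); between groups at 0.952 to 0.968 with a GF UV- array (27 pairs) and at 0.976 to 0.991 without (27 pairs). GF UV+ replicate 2 correlated better with the SPF UV+ arrays (mean 0.991) than with the other GF UV+ arrays (mean 0.988). The 2nd principal component held 20.2% of the variance and separated the unexposed SPF skins, at -40.0 to -41.6, from the rest, and the 3rd held 6.69%. The Y chromosome genes Eif2s3y and Kdm5d, named in advance for the test of sex, and Uty, chosen after its values were seen, had lowest log2 levels of 8.22, 7.22 and 8.28 over the 12 arrays. Xist lay between 2.80 and 3.21 log2 on the same arrays. These values argue against female mice on any of the 12 arrays, although the sources did not give the sex.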
